A study of Mus musculus with 36 samples.

How the data were processed

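Bulk RNA sequencing of liver and inguinal white adipose tissue (iWAT) was read from 36 libraries of 20 C57BL/6J mice, per the labels. The mice had spent 16 weeks fed ad libitum (AL), calorie-restricted (CR) or time-restricted without calorie restriction (TR), and each of the 6 groups of diet and tissue holds 6 libraries. Of the mice, 16 give both tissues and 4 give 1 tissue. An animal number is shared by CR and TR labels, and these libraries were counted as different mice. The sex of the mice is not given in the sources used here. Per the labels' protocols, total RNA was taken with Trizol and libraries were made with Illumina TruSeq.

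Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.20, aligned to GRCm38.p5 with STAR 2.5.3a and quantified with RSEM, whose version is not given. Per the file headers, the authors compared pairs of groups with edgeR generalized linear models; the edgeR version, filter, normalization method and annotation release are not given in the sources used here. The 12 tables, 6 of genes and 6 of transcripts, hold 1 comparison each, and they were used as deposited. The log2 values are the log2 fold change and the log2 mean CPM (read counts scaled to library size) fitted by the authors, per the file headers. The score values are the likelihood-ratio statistics of the authors' models, per the file headers. The p-value columns are the authors' unadjusted p-value and the FDR (the Benjamini-Hochberg adjusted p), per the file headers. Each comparison was normalized separately by the authors as far as the tables show, and values per library and depths are not in these tables, so no error per group and no interval from counts is given.

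The tables were checked first. The deposited p matched the chi-square tail (1 degree of freedom) of the deposited statistic to within 5e-06. Benjamini-Hochberg adjustment over the features of a table lay within 0.00626 of the deposited FDR. In each tissue CR minus AL less TR minus AL followed CR minus TR across genes with r of at least 0.999, with a median offset of 0.06 log2 units in iWAT genes and -0.0017 in liver genes. The median log2 fold change of the gene tables lay between -0.0381 and 0.0244. An approximate standard error was taken as the size of the log2 fold change over the square root of the likelihood-ratio statistic. Gene positions came from GENCODE M21 (GRCm38), where all looked-up identifiers were matched by their identifier.

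The comparisons, gene lists, naming rule and first alternatives were fixed before the data were examined. The design had planned models of counts, and named the authors' deposited FDR under 0.05 (2-sided, over all features of a table) as the test if only comparisons were given, which is what was used. The gene lists were 37 in liver and 34 in iWAT, counting marker lists of other cell types. For each list the main result is the number of members past the FDR in each direction and their median log2 fold change, beside the number adjusted over the list alone. A set test, cameraPR of limma 3.58.1 in R 4.3.3, was added after the data were seen. It ran on the signed square root of the likelihood-ratio statistic with a preset correlation of 0.01 and again of 0.05, over lists of at least 5 measured genes, with Benjamini-Hochberg adjustment over the lists of a comparison. An estimated correlation and fry need values per library and were not run. Every set call printed in the report as moved held at 0.05. Genes of a list can vary together more than these presets allow, and the set p-values would then be too small.

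The named genes are, for each comparison, the 6 highest and 6 lowest log2 fold changes past the FDR with a log2 mean CPM of at least 2.3, predicted genes left out. To these are added up to 4 members with the smallest adjusted p from each list described, and 13 genes per tissue named whatever their values. Some genes that the rule names are not reported here. Members named because a count was 5 or fewer, and genes the text says so of, were chosen after their values were seen.

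The overlap of the CR and TR responses was set against independent lists of the same sizes and against simulated diets. In the simulation (100 draws), log2 fold changes without any effect were drawn with the approximate standard errors and a shared AL group. Each gene was drawn independently of the others, so the range over the draws takes no account of genes that vary together between mice. Splitting the AL mice needs values per library and was not run. Approximate 95% intervals used the approximate standard error. The planned interaction of diet and tissue was replaced by an approximate test: the difference of the iWAT and liver log2 fold changes over the root of the summed squared standard errors, 2-sided, Benjamini-Hochberg adjusted over the genes measured in both tissues. Both tissues of a mouse were taken as uncorrelated, with 0.3 and -0.3 as alternatives. Liver-enriched genes, defined after the data were seen, are the 389 genes with a mean implied liver level of at least 50 CPM and at least 16 times the iWAT level, where group levels were implied by the deposited means and folds.

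The steps were tested on simulated data with the median spread of each table and 200 changed genes. More genes than this were called against AL, which makes the adjusted cutoff less strict there, so recovery in those comparisons can be higher. Genes changed by 1 log2 unit were recovered in 97.1% to 98.1% of cases in liver and 21.2% to 31.6% in iWAT. At 2 log2 units the share was 100% in liver and 95.0% to 98.1% in iWAT. False calls numbered 6 to 12 per comparison. For the tissue difference, 19.3% (CR) and 9.26% (TR) were recovered at 1 log2 unit and 95.5% and 84.8% at 2. False calls of that test numbered 13 in CR and 5 in TR. A simulated covariance of 0.1 was estimated as 0.0995 in liver and 0.0910 in iWAT. Of 40 simulated lists, cameraPR called the 1 shifted list and 0 of the others.

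Alternatives were a mean of at least 5 CPM, an absolute log2 fold change of at least 1, an adjusted p of 0.01, recentring on the median, adjustment over the table or the list, and leaving out the liver-enriched genes and muscle markers. Tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.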

Results

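Total RNA from the liver and the inguinal white adipose tissue (iWAT, a subcutaneous fat depot) of C57BL/6J mice was sequenced after 16 weeks on 3 diets. Mice fed ad libitum (AL) were the controls, a calorie-restricted group (CR) received fewer calories, and a time-restricted group (TR) ate without calorie restriction in a limited part of the day. Each of the 6 groups of diet and tissue holds 6 libraries, which makes 36 libraries in all. Setting TR beside CR addresses whether a daily fast without fewer calories gives the transcriptional response of calorie restriction. Sampling times are not given in the sources used here. Effects of the time since the last meal therefore cannot be told apart from those of the diets, in any comparison below. The values are the authors' comparisons of groups, so levels per library, their spread and the number of mice that show a direction are not given here, and the depth per library is unknown. The median approximate standard error of a log2 fold change, derived from the deposited statistics, was 0.142 to 0.153 in liver and 0.318 to 0.366 in iWAT. A gene is said to rise or fall only where the authors' adjusted p was under 0.05, and log2 fold changes are written as CR minus AL, TR minus AL or CR minus TR.

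In the liver, genes of fatty acid and triglyceride synthesis rose on both diets while many genes of cholesterol synthesis, targets of PPARalpha and subunits of the proteasome fell. Against AL, 1409 of 12636 genes changed in CR, 731 higher and 678 lower, and 2397 of 12691 changed in TR, 1186 higher and 1211 lower. The gene with the smallest adjusted p in the synthesis list was Pnpla3, a triglyceride lipase-family gene of hepatocytes that follows lipogenic feeding (ENSMUSG00000041653, GRCm38 chromosome 15 from 84167837 to 84187236), with a log2 fold change of 4.76 in CR (adjusted p = 1.1e-55) and 4.61 in TR (adjusted p = 5.7e-39) in the authors' deposited table of each diet. Of 27 measured members of that list, 19 rose in CR and 21 in TR, with 1, Elovl5, lower on both diets, and the median log2 fold changes were 0.72 and 0.89. Adjusted over the list alone, 23 rose in CR and 21 in TR. As a set the list moved up against the other genes, with adjusted p = 3.7e-31 in CR and adjusted p = 7.2e-24 in TR. Fasn, the fatty acid synthase, rose by 1.61 in CR and 1.96 in TR, and Srebf1, which encodes the transcription factor SREBP1, rose by 1.69 and 1.94 in the authors' deposited table of each diet. Acly, which makes cytosolic acetyl-CoA, rose by 1.34 and 1.01, and Elovl6, a fatty acid elongase, by 1.61 and 1.83 in the authors' deposited table of each diet.

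Cholesterol synthesis and SREBP2 target genes moved the other way in the liver. Of 25 members, 10 fell and 3 rose in CR, and 13 fell and 2 rose in TR, with medians of -0.37 and -0.60. Adjusted over the list alone, 13 fell in CR and 15 in TR. The set moved down with adjusted p = 5.8e-09 in CR and adjusted p = 5.6e-10 in TR. Hmgcs1, the cytosolic HMG-CoA synthase, had log2 fold changes of -1.83 in CR and -2.21 in TR, and Msmo1, a sterol demethylase, had -1.66 and -2.02 in the authors' deposited table of each diet. The members that rose were Ebp, Pmvk and Insig1 in CR and Ebp and Tm7sf2 in TR, each a gene of the same pathway or its feedback control, named after their values were seen.

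Of 34 PPARalpha targets and genes of fatty acid oxidation, 15 fell and 3 rose in the liver in CR, and 14 fell and 3 rose in TR. Adjusted over the list alone, 18 fell in CR and 15 in TR. The medians were -0.27 and -0.22, and the set moved down with adjusted p = 2.4e-16 and adjusted p = 4.2e-10. The omega-hydroxylase gene Cyp4a14 (ENSMUSG00000028715, GRCm38 chromosome 4 from 115486200 to 115496142) had a log2 fold change of -3.24 in CR (adjusted p = 3.0e-42) and -3.02 in TR (adjusted p = 6.3e-39) in the authors' deposited table of each diet. Cidec, a lipid droplet gene, had -2.65 and -2.85, and Cpt1a, the mitochondrial gatekeeper of fatty acid oxidation, had -0.51 and -0.50 in the authors' deposited table of each diet. Fgf21, a hormone of the fasted liver, had -2.06 in CR and -1.47 in TR, both past the threshold in the authors' deposited table of each diet. The 3 members that rose on both diets were Pdk4, Angptl4 and Acot3.

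Parts of other liver groups changed on both diets. Among 38 proteasome subunits, 17 fell in CR and 22 fell in TR, with 1, Psmb10, higher in TR; adjusted over the list alone, 26 and 27 fell. The proteasome set moved down with adjusted p = 1.8e-13 and adjusted p = 4.6e-14, and Psma5 had log2 fold changes of -0.70 and -0.84 in the authors' deposited table of each diet. Of 26 genes of cytochrome P450 and xenobiotic metabolism, 11 rose in CR, where Nqo1 fell, and 15 rose in TR, where Ugt2b35 fell, 18 and 15 when adjusted over the list alone, and Cyp1a2 rose by 1.11 and 1.19 in the authors' deposited table of each diet. Members of the respiratory chain and cytosolic ribosomal proteins shifted slightly upward, with medians of 0.22 and 0.25 in CR and 0.24 and 0.26 in TR; 6 of 74 respiratory genes and 5 of 81 ribosomal genes (Rpl22l1, Rpl27a, Rpl39, Rpl38 and Rpl12) rose in CR, and 17 and 11 rose in TR. Adjusted over the list alone, 4 and 23 respiratory genes rose in CR and TR, and 2 ribosomal genes on each diet. The shares called in CR lay below that of all liver genes, 1409 of 12636. In TR this held for the ribosomal genes, against 2397 of 12691. By cameraPR both sets moved up, with adjusted p = 6.8e-09 and 5.9e-10 in CR and 1.0e-08 and 5.0e-08 in TR. G6pc, the last enzyme of glucose output, rose by 1.84 and 1.82, and Igf1 by 0.62 and 0.55, while Pck1 had 0.36 (adjusted p = 0.56) and -0.22 (adjusted p = 0.47) in the authors' deposited table of each diet.

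The largest changes of the liver also held female-biased and Mup genes. Among the highest in CR by the naming rule were Cyp2b9 (5.69), Pnpla3, Hamp2 (3.55), Thrsp (3.42) and Chrna4 (2.85) in the authors' deposited table. Mup15 and Mup17, with -8.19 and -7.61 in CR and -10.45 and -9.44 in TR in the authors' deposited table of each diet, were the lowest on both diets.

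Clock genes of the liver changed in both directions. Of 19 members, 6 rose and 5 fell in CR, and the 5 that fell, Bhlhe41, Ciart, Dbp, Nr1d1 and Nr1d2, fell in TR too. When adjusted over the list alone, 8 rose and 5 fell in CR, and 7 and 5 in TR. The repressor Nr1d1 had log2 fold changes of -2.61 and -2.67, and the output factor Dbp had -2.49 and -2.79, while Cry1 rose by 1.97 and 1.79 and Per2 by 0.92 and 1.23 in the authors' deposited table of each diet. Arntl rose by 1.03 in CR (adjusted p = 0.0031), and its value in TR was 0.73 (adjusted p = 0.051) in the authors' deposited table.

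The CR and TR responses of the liver overlapped. Of the 12541 genes in both tables, 552 rose on both diets and 538 fell on both, where independent lists of these sizes would share 66.4 and 65.5 genes, a number that takes no account of the AL libraries common to both comparisons. The shared genes made up 77.8% of the CR calls and 46.1% of the TR calls. Only Elovl3 and Tuba8 changed in opposite directions, and both were named by the rule for CR minus TR. Across genes, which are not independent replicates, the log2 fold changes of the diets had r = 0.847 and a covariance of 0.152 over the 12389 genes in all 3 tables. Through these AL libraries, simulated diets without any effect gave a mean r of 0.516 and a covariance of at most 0.0227 in 100 draws. Genes were drawn independently, so this highest value is too low a bound if genes vary together between mice. Of 1060 genes shared in direction and present in the CR minus TR table, 1001 (94.4%) had an approximate 95% interval for CR minus TR within 1 log2 unit of 0, and 684 (64.5%) within 0.5. These genes were chosen for changing in the same direction on both diets, which favours small differences between them. The margin of 1 log2 unit is wide here: only 284 of 1409 CR calls and 448 of 2397 TR calls against AL reached that size.

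**Figure D1:**
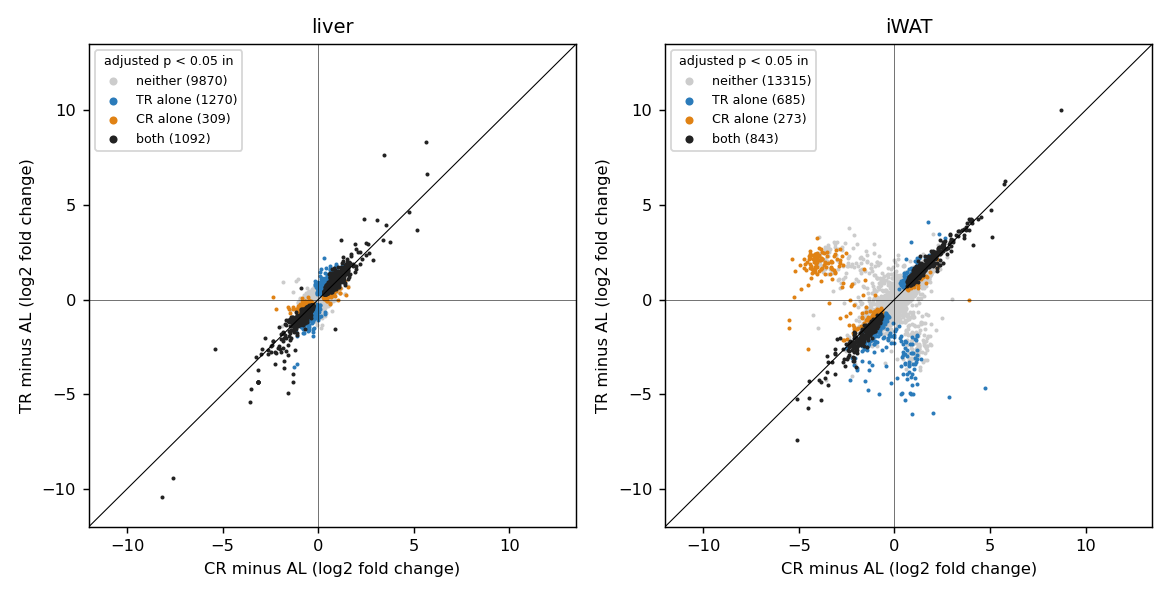
Log2 fold change of each gene in CR minus AL (horizontal axis) and TR minus AL (vertical axis), in liver and iWAT, coloured by the diets in which the authors' adjusted p was under 0.05. Of the genes in both tables, 1090 in liver and 843 in iWAT changed on both diets in the same direction, and in iWAT clouds of points off the diagonal hold liver-enriched genes (upper left) and skeletal muscle genes (lower right).

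Directly compared, CR and TR livers differed in 59 of 12593 genes, 20 higher and 39 lower in CR, and sex-biased genes stood at both ends. Major urinary protein genes, which are secreted pheromone carriers of male mouse liver, were higher in CR than in TR: 8 of the 17 Mup genes measured passed the threshold and none was lower. Mup7 (ENSMUSG00000073842, GRCm38 chromosome 4 from 60066469 to 60070475) had a log2 fold change of 3.37 in CR minus TR (adjusted p = 0.0055), from -1.58 in CR minus AL and -4.95 in TR minus AL, in the authors' deposited table of each comparison. Elovl3, a male-biased elongase, rose by 0.91 in CR, fell in TR with -1.58, and had 2.48 in CR minus TR (adjusted p = 1.9e-04) in the authors' deposited table of each comparison. At the other end stood Cyp2b13 with -4.97 and Cyp2a4 with -4.18 in CR minus TR in the authors' deposited table. Of these, only Cyp2b13 is among the members of the sex-biased lists that passed the threshold. Over the 27 male-biased genes, 5 were higher in CR than in TR (Elovl3, Mup1, Mup7, Mup11 and Mup12), 10 when adjusted over the list alone, with a median of 0.67 (adjusted p = 1.4e-18 as a set). Over the 15 female-biased genes, 3 were lower in CR (A1bg, Cyp2b13 and Fmo2), 9 when adjusted over the list alone, with a median of -0.73 (adjusted p = 5.6e-11 as a set). Against AL, 13 male-biased genes fell and 0 rose in TR, 14 and 0 when adjusted over the list alone (adjusted p = 1.0e-08 as a set). In CR 7 fell and 4 rose (Egfr, Elovl3, Nudt7 and Ugt2b1), 9 and 5 when adjusted over the list alone; there the median of 0.03 and the downward direction of the set test (adjusted p = 0.47) differ in sign. Of the female-biased genes, 8 of 14 rose in TR (9 when adjusted over the list alone), and in CR Acot3, Cyp2b9 and Cyp39a1 were among those that rose and Abcd2 fell. Reads of the Mup and Cyp2 families can be shared among close paralogs, and the fitted folds of Cyp2b13, Mup15 and Mup17 rest on a group near 0 and depend on the prior count.

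Of the 59 genes that differed between CR and TR livers, 12 were on the sex-biased lists or Mup genes and 47 were not. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had -0.58 (adjusted p = 0.022) in the authors' deposited table of CR minus TR. It rose in TR, and its value in CR minus AL was 0.21 (adjusted p = 0.54). Igfbp2 had -0.79 (adjusted p = 2.0e-04) in the authors' deposited table of CR minus TR. Of the genes called against AL in TR alone, 25 of the 1287 in the CR minus TR table passed the threshold there and 389 had an unadjusted p under 0.05; of those called in CR alone, 6 and 88 of 311 did. For genes called on neither diet the numbers were 11 and 645 of 9772, and for those called on both diets 16 and 121 of 1062. The median absolute log2 fold changes of CR minus TR in these groups of genes were 0.23, 0.22, 0.11 and 0.11. The calls against AL and CR minus TR share libraries, so these shares are not independent of the choice of genes.

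In iWAT, many genes of fatty acid synthesis, fatty acid oxidation, the respiratory chain and thermogenesis rose on both diets, and part of the genes of the extracellular matrix and of the markers of adipocyte size fell. Against AL, 1117 of 15295 genes changed in CR, 539 higher and 578 lower, and 1535 of 15356 changed in TR, 731 higher and 804 lower. Hepatocyte and muscle transcripts differed in these samples too: 118 of the 578 genes lower in CR were liver-enriched genes, and 7 of 9 hepatocyte markers fell in CR with a median of -3.78. In TR the median of the same 9 markers was 2.11 with 0 past the threshold in the authors' edgeR test (1 had an unadjusted p under 0.05), and 5 of 16 skeletal muscle markers fell (Acta1, Mb, Mybpc1, Myh1 and Myh2), 16 when adjusted over the list alone, with a median of -2.84. In CR the muscle markers had a median of 1.22 with 0 past the threshold and 0 at an unadjusted p under 0.05. Leaving out the liver-enriched genes and the muscle markers left 999 genes in CR and 1526 in TR, a choice made after the data were seen.

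Genes of fatty acid and triglyceride synthesis in iWAT rose together. Of 30 members measured in CR, 21 rose and 0 fell, with a median of 1.65; of 31 measured in TR, 22 rose and 0 fell, with a median of 1.77. These counts were 25 and 28 when adjusted over the list alone. The set moved up with adjusted p = 1.9e-29 and adjusted p = 2.0e-48. Elovl6 (ENSMUSG00000041220, GRCm38 chromosome 3 from 129532355 to 129638495) rose by 4.02 in CR (adjusted p = 2.2e-13) and 4.27 in TR (adjusted p = 7.1e-18), and Acss2, which makes acetyl-CoA from acetate, by 3.53 and 3.70 in the authors' deposited table of each diet. Fasn rose by 2.61 and 2.71, Acly by 2.78 and 2.74, and Acaca, a cytosolic acetyl-CoA carboxylase, by 2.37 and 2.55 in the authors' deposited table of each diet. The regulators Srebf1 and Mlxipl did not pass the threshold, with 0.82 (adjusted p = 0.17) and 0.75 (adjusted p = 0.19) in CR, and 0.88 (adjusted p = 0.13) and 0.65 (adjusted p = 0.24) in TR, in the authors' deposited table of each diet.

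Oxidative genes of iWAT rose beside the synthetic ones. Of 75 respiratory chain genes, 52 rose in CR and 62 in TR, 71 and 70 when adjusted over the list alone, with medians of 0.93 and 1.13 and 0 lower on either diet (adjusted p = 8.9e-42 and adjusted p = 1.6e-42 as a set). Of 20 genes of fatty acid oxidation, 13 rose in CR and 12 in TR, 14 and 15 when adjusted over the list alone, where Cpt1a was lower in CR, with medians of 0.95 and 1.05. Hadhb, a subunit of the mitochondrial trifunctional protein, rose by 1.71 and 1.74 in the authors' deposited table of each diet. Among 26 thermogenic and beige adipocyte genes, 12 rose and 2 fell in CR, and 12 rose and 3 fell in TR, and the set moved up with adjusted p = 4.4e-09 and adjusted p = 9.1e-05. When adjusted over the list alone, 13 rose and 2 fell in CR, and 12 rose and 4 fell in TR. Ucp1, the uncoupling protein of brown and beige fat (ENSMUSG00000031710, GRCm38 chromosome 8 from 83290352 to 83298452), rose by 4.13 in CR (adjusted p = 1.3e-04) and 2.88 in TR (adjusted p = 0.010), and Cidea, a lipid droplet gene of the same cells, by 4.08 and 4.05 in the authors' deposited table of each diet. The Ucp1 folds are imprecise, with approximate standard errors of 0.86 and 0.83. Its CR minus TR value was 1.18 (adjusted p = 0.44) in the authors' edgeR test. The members that fell were Ebf2 and Gatm on both diets and Fabp3, which is also a muscle gene, in TR.

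Pdzk1ip1, with 5.72 in CR and 6.13 in TR, and Elovl3, with 4.55 and 4.37, had the highest folds of iWAT by the naming rule in the authors' deposited table of each diet. The lowest in CR were genes of the liver, Cyp4a14 (-5.51), Cyp4a10 (-5.49), Bhmt (-5.27), Mup20 (-4.89), Mat1a (-4.72) and Apoa5 (-4.54), and the lowest in TR held the muscle genes Myh1 (-6.06), Mybpc1 (-5.28) and Trim63 (-5.01) beside Zim1 (-5.72), Slc5a7 (-5.29) and Peg3, in the authors' deposited table of each diet.

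Part of the genes tied to the size and the matrix of fat tissue fell. The imprinted gene Peg3 (ENSMUSG00000002265, GRCm38 chromosome 7 from 6703892 to 6730431) had -4.44 in CR (adjusted p = 5.1e-19) and -5.19 in TR (adjusted p = 3.7e-34), and Mest, another imprinted gene, had -3.86 and -4.33 in the authors' deposited table of each diet. Of 12 markers of adipocyte size, 6 fell in CR and 6 in TR, 9 and 9 when adjusted over the list alone, with medians of -1.08 and -1.12; with that adjustment Phlda3 was higher in TR. Of 25 matrix genes, 7 fell on each diet, 9 in CR and 10 in TR when adjusted over the list alone, with medians of -0.59 and -0.68; Thbs1 had -2.22 and -2.64, and Lox, which crosslinks collagen, had -1.64 and -2.08 in the authors' deposited table of each diet. Of 14 genes of adipose progenitors, cells that make matrix, 13 lay below 0 on each diet, with medians of -0.59 and -0.63. Anxa3 fell on both diets and Pdgfra and Zfp423 in TR, and 3 fell on each diet when adjusted over the list alone. That set moved down in CR with adjusted p = 0.0019, and its call in TR (adjusted p = 0.011) was lost at a preset correlation of 0.05, with adjusted p = 0.0503. Markers of other non-adipocyte cells lay below 0 too, 10 of 10 of endothelium and 9 of 9 of Schwann cells and nerve on each diet and 16 and 15 of 18 of macrophages, while those of lymphocytes lay above it. Whether fewer of these cells or less matrix per cell underlies the fall was not tested. The adipokine gene Lep had -1.0 in CR (adjusted p = 0.16) and -0.96 in TR (adjusted p = 0.030), and Adipoq had -0.15 (adjusted p = 0.88) and 0.09 (adjusted p = 0.88) in the authors' deposited table of each diet. Pparg, the regulator of fat cell identity, had 0.04 (adjusted p = 0.96) and 0.07 (adjusted p = 0.92), and the lipase gene Pnpla2 had 0.38 (adjusted p = 0.67) and 0.64 (adjusted p = 0.088) in the authors' deposited table of each diet.

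Of 20 clock genes in iWAT, Bhlhe40, Bhlhe41, Cry1 and Nfil3 were among those that rose in CR, where Nr1d1 fell, and 6 rose and 3 fell (Clock, Nr1d1 and Nr1d2) in TR. When adjusted over the list alone, 7 rose on each diet, and 2 fell in CR and 4 in TR. Nr1d1 had -1.16 in CR and -2.01 in TR, and Bhlhe40 rose by 1.97 and 2.11 in the authors' deposited table of each diet. Dbp had 0.26 (adjusted p = 0.74) and 0.26 (adjusted p = 0.75), and Arntl had -0.08 (adjusted p = 0.93) and -0.39 (adjusted p = 0.51) in the authors' deposited table of each diet.

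**Figure D2:**
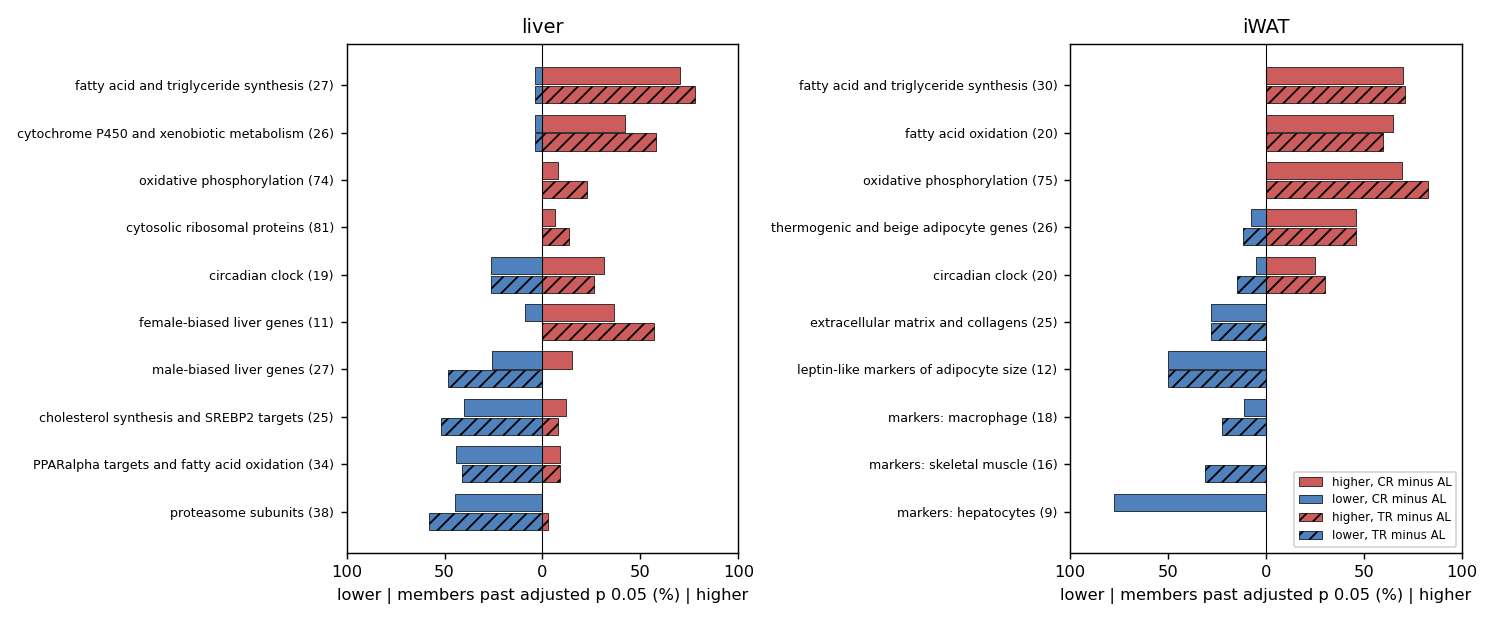
Percent of the measured members of each gene list that were higher (right of 0) or lower (left of 0) at an adjusted p under 0.05 in CR minus AL (plain bars) and TR minus AL (hatched bars), for liver and iWAT. Bars are percents of the members measured in each comparison, the number in parentheses is for CR minus AL, and 52 of 75 respiratory chain genes were higher in iWAT in CR against 6 of 74 in liver.

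The iWAT responses to CR and TR overlapped too. Of 15116 genes in both tables, 481 rose and 362 fell on both diets, 0 changed in opposite directions, and independent lists would share 25.8 and 30.7. Across the 14572 genes in all 3 tables r was 0.559, below the mean of 0.590 that simulated diets without effect gave through the shared AL libraries, while the covariance of 0.327 lay above the highest simulated covariance of 0.132. The simulated genes were independent, whereas hepatocyte and muscle transcripts varied together in these samples, so that highest value is no firm bound. With the liver-enriched genes and muscle markers left out, r was 0.821 against a simulated mean of 0.612. Of 817 shared genes present in the CR minus TR table, 0 differed between the diets at the threshold and 21 had an unadjusted p under 0.05. The change was larger in TR for 719 of the 817, and the median difference in size over all of them was 0.21. Standard errors were larger in TR minus AL (median 0.366 against 0.318). Passing the threshold there selects larger folds, so this count cannot tell whether TR acts more strongly. The approximate 95% interval of CR minus TR lay within 1 log2 unit of 0 for 617 of the 817 genes (75.5%) and within 0.5 for 4 (0.490%), so smaller differences were not detectable.

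CR and TR iWAT differed in 135 of 14699 genes, and nearly all were liver or muscle transcripts. Of the 126 genes lower in CR, 125 were liver-enriched, and all 9 hepatocyte markers were lower in CR, with a median of -5.95. Of the 9 genes higher in CR, 3 were on the muscle list (Myh1 with 6.98, Mb with 5.96 and Mybpc1 with 5.84 in the authors' deposited table), and Fabp3, Actn2, Nexn, Tnnt1 and Cavin4, which striated muscle also expresses, were higher as well. The remaining genes were Gm45837 (10.41) and Mmd2 (-1.88), named with Tnnt1 and Cavin4 after their values were seen in the authors' deposited table. Among the lowest liver transcripts named by the rule were Hsd17b13 (-7.48), a lipid droplet enzyme, and the urea cycle gene Cps1 (-6.84) in the authors' deposited table. Without liver-enriched genes and muscle markers, the count was 7. Among lists, respiratory chain genes lay lower in CR than in TR, with a median of -0.28, 0 of 75 past the threshold in the authors' edgeR test, 0 at an unadjusted p under 0.05 and adjusted p = 1.8e-09 as a set. Synthesis genes had a median of -0.25 with 1, the liver-enriched Pklr, past the threshold (adjusted p = 6.1e-05 as a set). Chaperones lay below 0 in 25 of 25, with a median of -0.31, 0 past the threshold in the authors' edgeR test, 2 at an unadjusted p under 0.05 and adjusted p = 1.2e-05 as a set. Markers of erythroid cells, another cell type, lay below 0 in 5 of 5, with a median of -0.64, 0 past the threshold in that test, 1 at an unadjusted p under 0.05 and adjusted p = 2.1e-04 as a set. Adipocyte markers lay below 0 in 9 of 9, with a median of -0.31, 0 past the threshold in that test, 0 at an unadjusted p under 0.05 and adjusted p = 0.057 as a set. Mature adipocyte genes did so in 15 of 19, with a median of -0.19. Downward shifts of this size were thus not particular to the pathways above. Thermogenic and beige adipocyte genes went the other way, with 16 of 26 above 0, a median of 0.11 and 1, Fabp3, past the threshold. Their upward set call (adjusted p = 0.012 by cameraPR) was lost at a preset correlation of 0.05, with adjusted p = 0.10.

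**Figure D3:**
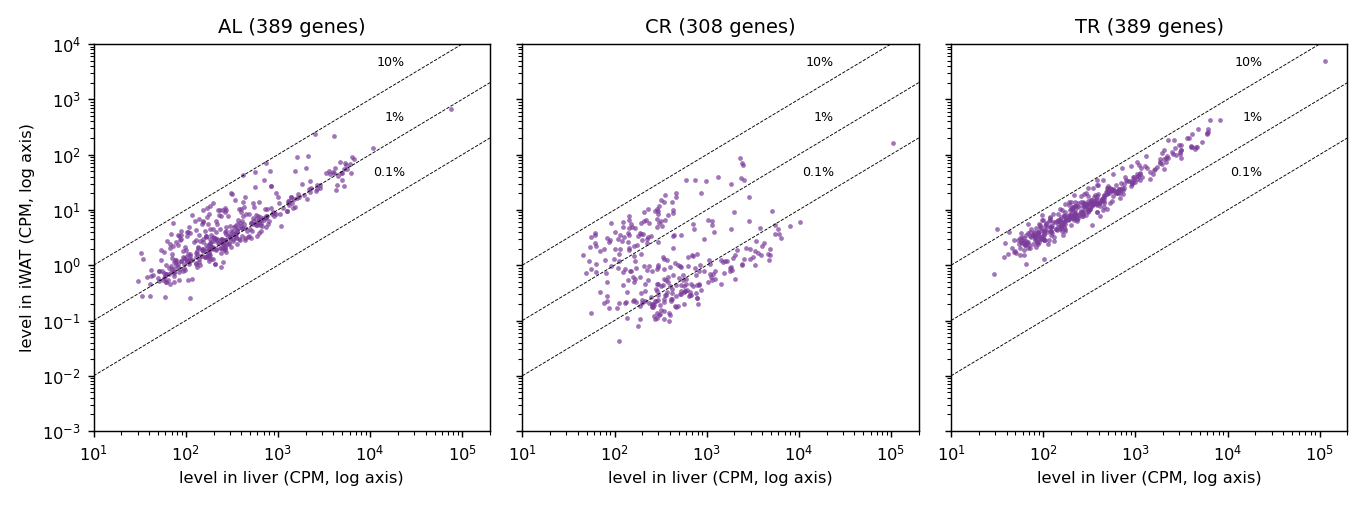
Level of each liver-enriched gene in iWAT (vertical axis, CPM, log scale) against its level in liver (horizontal axis, same unit and scale) in AL, CR and TR, as implied by the deposited mean levels and folds; dashed lines mark 10%, 1% and 0.1% of the liver level. The median iWAT level was 1.18% of the liver level in AL, 0.177% in CR and 3.95% in TR, and over the 9 hepatocyte markers 1.22%, 0.0745% and 4.25%. In CR the points cover 308 genes against 389 in AL and TR and scatter widely, with a standard deviation of the log2 ratio of 2.38 and r = 0.255.

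By an approximate test of the difference, the diet effect differed between iWAT and liver for 809 of 12012 genes in CR (371 higher and 438 lower in iWAT) and for 953 of 12201 in TR (508 higher and 445 lower). Without liver-enriched genes and muscle markers the counts were 619 and 969. The test takes the tissues of a mouse as uncorrelated, and the counts depend on this: a correlation of 0.3 gave 1393 in CR and 1555 in TR, and -0.3 gave 459 and 586. With a mean of at least 5 CPM they were 504 and 696. Most genes called in both tissues moved the same way, 118 of 169 in CR and 207 of 301 in TR; r between the tissues across genes was 0.077 and 0.185. Cholesterol synthesis genes, part of which fell in the liver, mostly rose in iWAT: 17 of 24 in CR and 19 of 25 in TR, with medians of 1.31 and 1.69, and 0 fell. Not all members were opposite. Insig1 and Pmvk in CR and Ebp and Tm7sf2 in TR rose in both tissues. Hmgcs1, which fell in the liver, had -0.29 in CR (adjusted p = 0.64) and -0.61 in TR (adjusted p = 0.26) in iWAT in the authors' edgeR test. The difference from the liver passed the threshold for 19 of 24 in CR and 20 of 25 in TR, more genes than fell in the liver. The list was planned for the liver alone and was looked at in iWAT after the values were seen. Lss, the lanosterol synthase, rose by 2.17 in CR and 2.22 in TR in iWAT in the authors' deposited table of each diet, and had -0.81 and -1.14 in the liver. For the iWAT list of fatty acid oxidation, the difference passed the threshold for 14 of 20 genes on each diet, all higher in iWAT, and in the liver 7 of 20 fell and 2 rose (Hibadh and Pdk4) on each diet.

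At the level of transcripts, 703 of 26448 changed in liver in CR (384 higher), 1050 of 26648 in TR (521 higher) and 84 of 26042 between CR and TR (41 higher in CR). In iWAT the counts were 838 of 34231 (485 higher), 1214 of 34175 (695 higher) and 132 of 31936 (32 higher in CR). Most transcripts called against AL had a parent gene called in the same direction, 83.3% in liver and 80.4% in iWAT in CR, and 86.2% and 84.8% in TR. Between CR and TR this share was 22.6% in liver and 53.8% in iWAT. The transcript ENSMUST00000110372 of Acsl1, a long-chain acyl-CoA synthetase gene, rose by 2.22 in TR liver while its gene had 0.09 (adjusted p = 0.72), and ENSMUST00000113825 of Pcx, the pyruvate carboxylase gene, had -1.88 in CR liver while its gene had -0.27 (adjusted p = 0.33), in the authors' deposited table of each level; both were named after their values were seen.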

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

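The tissue differences below come from the approximate test that replaced the planned interaction, and all tests of an explanation in this part were chosen after the result was seen. A difference between the tissues singled out genes called in liver and iWAT in opposite directions: 51 in CR minus AL and 94 in TR minus AL. Calls in opposite directions nearly entail a difference, so its test adds nothing for these genes. Without liver-enriched genes and muscle markers 42 and 94 were left, and those lower in iWAT and higher in liver numbered 13 rather than 22 in CR. In CR, iWAT minus liver was 2.98 for Lss, 3.31 for 2010003K11Rik and 2.58 for Idi1. In TR it was 3.40 for Msmo1, 4.09 for Mvd and 3.36 for Lss. A comparison of single samples with the rest of their group, and counts over other splits of the samples, need values per library and were not possible with the tables used here, so chance in the grouping of mice was not tested beyond the authors' own test.

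The genes lower in CR than in TR iWAT were liver genes, with 125 of 126 liver-enriched, and TR iWAT stood near a fixed share of the liver level: the standard deviation of the log2 ratio of TR iWAT to TR liver was 0.388 over these genes. This is consistent with liver RNA in TR iWAT libraries. Their log2 levels in TR iWAT followed those in TR liver with r = 0.974, which argues against a response of the cells of iWAT set gene by gene. Alb, the most abundant of them, stood at an implied 678 CPM in AL, 163 in CR and 4841 in TR iWAT, while the median levels of liver-enriched genes were 1.18%, 0.177% and 3.95% of those in liver. In CR this was no fixed share: over the 308 genes with an implied level in CR iWAT the standard deviation of the log2 ratio was 2.38 with r = 0.255, and the 9 hepatocyte markers gave 0.0745%. AL iWAT stood nearer a fixed share, with 0.904 and r = 0.881 over 389 liver-enriched genes and 0.301 and r = 0.988 over the 9 markers. Liver RNA in AL libraries may thus also underlie the 118 liver-enriched genes lower in CR than in AL iWAT, which was not tested. Which libraries carry the liver RNA, and whether it entered at dissection, library preparation or sequencing, stays open. For the genes higher in CR, all 16 measured skeletal muscle markers lay below 0 in TR minus AL, which is consistent with different amounts of muscle in the samples, and Acta1 stood at 466, 866 and 62.2 CPM in AL, CR and TR.

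Many Mup genes and part of the other male-biased genes were lower in TR liver than in AL. Against CR, 8 of 17 Mup genes were lower in TR, and of the other male-biased genes Elovl3 alone passed the threshold. The Mup genes fell in CR too: of 19 measured, 14 fell and Mup22 rose in CR and 16 fell in TR, and log2 of their summed level of CR over AL was -0.49. Reads moving between Mup paralogs would leave their sum in place, but log2 of the summed Mup level of TR over AL was -1.18, which argues against it as the whole cause. Groups wholly of different sex are argued against by the Y-linked genes: 4 of 4 had an approximate interval within 1 log2 unit of 0 in TR minus AL, with 0 past the threshold in the authors' edgeR test and 0 at an unadjusted p under 0.05. A minority of mice of the other sex within a group could stay inside that margin, so it cannot exclude them. Yet a minority without any Mup transcripts would lower a group mean by less than 1 log2 unit if the others were unchanged. The median over the 19 Mup genes was -2.95 in TR minus AL. This argues against such a minority as the whole cause of the Mup fall in TR. Of the 20 measured male-biased genes other than Mup, 95% lay above 0 in CR minus TR, with a median of 0.62 and Elovl3 past the threshold, so a wider change of sex-biased genes may be present. The sizes of single paralogs stay uncertain, and a biological cause of the change was not tested.

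Transcripts with very large folds were common between CR and TR livers: 50 of the 84 called had an absolute log2 fold change of at least 5. For 96% of these the parent gene lay within 0.5 log2 units of 0. Reads assigned to another transcript of the gene could give this, and so would a switch of transcripts in the tissue, so these cannot be told apart without values per library. Such folds depend on the prior count of the authors' fit.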

How the results depend on the processing

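Settings and tests chosen after seeing the data are the adjusted p of 0.01 for counts (for the overlap it was planned), the minimum of 5 CPM for gene lists and named genes, recentring, adjustment over the list or table, the liver and muscle filter, the preset correlations and the tissue correlations. Of 93 alternative values of counts, overlaps and covariances, 63 lay within 1.5 times the reported value; the others follow, mostly through a stricter threshold or fewer features tested. With an absolute log2 fold change of at least 1, liver counts were 284 (CR minus AL), 448 (TR minus AL) and 24 (CR minus TR). At an adjusted p of 0.01 liver genes numbered 822, 1424 and 29, iWAT genes 589, 791 and 1, liver transcripts 445, 674 and 47, iWAT transcripts 450, 651 and 51, the overlap 648 in liver and 466 in iWAT, and list members in CR minus TR iWAT 0. With at least 5 CPM, CR minus TR transcripts numbered 32 in liver and 81 in iWAT, list members in CR minus TR iWAT 1, and the tissue difference in CR 504. Without liver-enriched genes and muscle markers CR minus TR iWAT gave 7. Adjusted over the list alone, CR minus TR liver lists gave 31 members, against 12. With a preset correlation of 0.05, 9 lists were called in liver CR minus AL, against 14, and 9 in iWAT TR minus AL, against 15. An assumed correlation of 0.3 between tissues gave 1393 (CR) and 1555 (TR) genes, and -0.3 gave 459 and 586. Among genes named in the text, 745 of 752 alternative values kept their direction and side of the threshold and 0 reversed. Recentring put Nqo1 (CR minus AL, liver) and Nexn (CR minus TR, iWAT) short of it, with log2 fold changes of -0.51 and 3.05. With at least 5 CPM, Arntl (TR minus AL, liver), Hba-a1 (CR minus AL, liver) and Bhlhe41 (TR minus AL, iWAT) passed it, the last also when recentred. Recentring took Pdgfra (CR minus AL, iWAT) past it too, with -0.83.

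No paired analysis was possible because the tables used here give comparisons of groups and no values per library. For the same reason other scalings, no filter, DESeq2, limma-voom, fits of 2 diets, leaving out each replicate, leaving out the TR mice with 1 tissue, mouse blocks, estimated correlations, fry, splits of the AL mice and pseudocounts were not run. Whether a single library decides a result is therefore open. Depth per library is unknown. In iWAT, changes of 1 log2 unit were recovered in 21.2% to 31.6% of simulated cases, so smaller differences there were often not detectable.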

Other observations

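The counts of list members were planned, and all tests of the clock hypothesis and the set tests were chosen after the result was seen. In the liver, of 18 genes of sulfur amino acid and methionine metabolism, 7 fell in CR and 5 in TR (Bhmt, Cbs, Cdo1, Cth and Mat1a), with 2 higher in CR (Mpst and Pemt) and 3 in TR (Mpst, Pemt and Tst). With adjustment over the list alone, 7 fell and 2 rose in CR, and 7 fell and 4 rose in TR. Bhmt, which remethylates homocysteine, had -1.30 in CR and -1.09 in TR in the authors' deposited table of each diet. The set call in CR (adjusted p = 0.019) was lost at a preset correlation of 0.05, with adjusted p = 0.094, and in TR the set did not pass (adjusted p = 0.39 and adjusted p = 0.52 at these correlations). Of 27 genes of autophagy and lysosome, 5 fell in CR (Atg14, Gabarapl1, Map1lc3a, Sqstm1 and Tfe3) and 6 in TR, 6 on each diet when adjusted over the list alone. In TR, 8 of 24 chaperones fell, and Hspa1b and Hspb1 rose, with the same counts when adjusted over the list alone. As a set they did not pass in TR (adjusted p = 0.10 by cameraPR). In CR 0 passed the authors' edgeR test and 2 had an unadjusted p under 0.05. A difference of CR and TR in this list was not past the threshold for any gene (6 had an unadjusted p under 0.05). The acute phase genes Orm2 and Orm1 rose by 2.07 and 0.82 in CR and by 2.5 and 0.78 in TR, and Lbp had -0.73 and -0.64, in the authors' deposited table of each diet. Of the 5 adipocyte markers measured in liver, Cfd, Cidec and Pparg fell on both diets and Lipe rose in TR, with the same counts when adjusted over the list alone and medians of -0.66 and -0.61. In CR minus TR, Lipe had -0.40 (adjusted p = 0.12) in the authors' deposited table. This set moved down in CR (adjusted p = 0.0024, and 0.0057 at a preset correlation of 0.05), and its call in TR (adjusted p = 0.041) was lost at 0.05, with adjusted p = 0.070. Globin transcripts rose in liver on both diets: Hba-a2, Hbb-bs and Hbb-bt in CR, and these with Hba-a1 in TR.

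In iWAT, the macrophage markers Cd163 and Mrc1 fell in CR with -1.61 and -1.04, and in TR with -1.92 and -1.65 beside Itgam and Trem2 (2 in CR and 5 in TR when adjusted over the list alone), in the authors' deposited table of each diet. The 18 markers had a median of -0.45 on each diet (adjusted p = 1.9e-03 in CR and adjusted p = 2.1e-03 in TR as a set). Markers of lymphocytes lay on the other side: 16 of 16 of B cells and lymph node were above 0 on each diet, with medians of 1.10 in CR and 0.95 in TR, and 14 of 15 of T and NK cells, with medians of 0.95 and 0.59. In these lists 0 passed the authors' edgeR test on either diet, and 1 had an unadjusted p under 0.05, a T and NK cell marker in CR. Their set calls in CR (adjusted p = 0.029 and adjusted p = 0.040) were lost at a preset correlation of 0.05, with adjusted p = 0.10 and adjusted p = 0.11, and in TR the sets did not pass (adjusted p = 0.071 and adjusted p = 0.15). All 9 markers of Schwann cells and nerve lay below 0 on each diet, with medians of -0.85 and -0.61, and Prx was among those that fell in CR. Their set moved down in CR (adjusted p = 0.0019, and 0.0099 at a preset correlation of 0.05), and its call in TR (adjusted p = 0.035) was lost at 0.05, with adjusted p = 0.077. All 10 endothelial markers lay below 0 on each diet too, with medians of -0.33 and -0.34, and Tek, an endothelial receptor, fell on both. Their set moved down in CR (adjusted p = 0.013, and 0.041 at 0.05), and its call in TR (adjusted p = 0.0497) was lost, with adjusted p = 0.10. Bckdk and Pccb, of branched-chain amino acid catabolism, rose on both diets, with Mccc1 and Pcca in CR; the set calls (adjusted p = 0.0082 in CR and 0.0086 in TR) were lost at a preset correlation of 0.05, with adjusted p = 0.052 and adjusted p = 0.051. The proteasome, which fell in liver, had 5 of 37 subunits higher in iWAT in TR (Psma6, Psmb7, Psmb5, Psmb3 and Psmd5) and 0 past the authors' edgeR test in CR, where 6 had an unadjusted p under 0.05. On each diet 36 of 37 subunits lay above 0, with medians of 0.33 in CR and 0.44 in TR, and the set moved up with adjusted p = 8.1e-05 and adjusted p = 6.5e-06 (0.011 and 0.0036 at a preset correlation of 0.05). In CR minus TR the median was -0.20, with 0 past the authors' edgeR test, 0 at an unadjusted p under 0.05 and adjusted p = 2.4e-04 as a set (0.022 at 0.05).

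Values outside any list include the noncoding gene Rn7s1, with -2.38 in CR and -2.17 in TR liver, and Lars2, with -2.19 and -2.83, in the authors' deposited table of each diet, named after their values were seen.

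A hypothesis was that a shifted clock phase at sampling explains the clock genes that changed. It asked for genes of the Nr1d1 and Dbp arm below 0 and genes of the Arntl arm above 0, at least 10 of 13 on both diets. In liver 9 of the 12 measured genes lay on the side of their arm on each diet (Fisher's exact test, 2-sided, p = 0.222), so the mark of 10 was missed. In iWAT 4 of 13 did so on each diet (Fisher's exact test, p = 0.293), a count that includes genes near 0 such as Dbp and Arntl. Among genes past the threshold, whose values were seen before the test was chosen, 7 of 7 lay on the side of their arm in liver in CR and 6 of 7 in TR, with Usp2 on the other side. In iWAT these were 3 of 3 in CR (Cry1, Nfil3 and Nr1d1) and 4 of 6 in TR (these and Nr1d2, with Clock and Usp2 on the other side). The reading of both counts was changed after they were seen, from counting against the hypothesis to leaving it open; they lend it no support. Sampling times are not given in the sources used here.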
